A study of Arabidopsis thaliana with 6 samples.

How the data were processed

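RNA from ovules was sequenced on an Illumina HiSeq4000 as stranded total RNA libraries depleted of ribosomal RNA, per the labels. Per the submitters' processing notes, Trimmomatic, STAR, featureCounts of Subread 1.6.0 and DESeq2 were used with the TAIR10 genome. Per the file headers, the authors counted fragments per gene with featureCounts on the annotation of release 37, with strand setting 1 and fragment lengths checked, and these whole-number counts were deposited without normalization for 33977 genes. Per the file headers, a second deposited table holds counts per exon bin of a flattened annotation, with a fragment counted in every bin it overlaps, for 200285 bins in 32585 gene groups. Groups merge genes that overlap, and 6.15% of the bins lie in such groups.

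Another deposited table, in the column layout of IRFinder, gives for 118281 introns a mean depth (coverage), the count of reads spliced at both ends and the retention ratio, a fraction from 0 to 1. The ratio equalled the depth over the sum of the depth and the larger flanking splice count, within 0.001, in 80.0% of introns. This table names no sample, so no group was given to its values, the planned test between genotypes was not run, and its 10 other columns of values were not used. The authors' deposited table of their own comparison gives log2 fold changes, mean normalised signal and adjusted p-values in the columns of a DESeq2 result. All its p-values lie under 0.05, so it holds only genes past that threshold, and a positive log2 fold change means a higher level in the libraries labelled mutant.

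Samples were grouped by their titles. The labels call the replicates biological without saying whether they came from separate plants, so p-values measure the spread between these libraries, which may be technical in part. No pair of libraries of a group agreed within sampling noise (chi-square per gene from 5.06 to 89.4). In wild type replicate 1, 77.6% of the nonzero gene counts were even numbers, against 47.7% to 48.6% in the other libraries, and the ratio of bin counts to gene counts in genes of a single bin was 0.516, against 1.01 to 1.03. Its gene counts may therefore hold each fragment counted 2 times. They were used as deposited, and a fit with them halved was added after the data were examined. Exon bin counts totalled 7361474 in that library and 18706217 to 23086207 in the others.

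Coordinates are those of the files (TAIR10). Gene names came from the RefSeq annotation of TAIR10.1, in which 32548 of the genes were found by identifier, 99.95% of them with identical start and end. Gene counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust, TMM factors, filterByExpr, no covariate) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 14.9%. CPM values (counts scaled by library size) use TMM-scaled library sizes, and standard errors are the absolute log2 fold change over the square root of the F statistic. Intervals and floors cover counting error only. The Wilson intervals for shares of exon bin counts take each bin count as independent. A fragment is counted in every bin it overlaps, so these intervals are too narrow even for counting error. Exon bin usage was tested with diffSpliceDGE on bins with at least 10 counts in at least 3 libraries, in gene groups with at least 2 such bins, per bin and per gene (Simes). A usage log2 fold change is relative to the other bins of the group. Figures and other tables used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

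The 19 written gene lists with 278 members and the 2 lists taken from the annotation (defensin-like and organelle-encoded genes), the tests and the rule for named genes were set before the data were examined. The rule named PRP8A, PRP8B, MYB98, LURE1.1 to LURE1.5, FER, LRE and NTA, and the 10 genes of largest absolute log2 fold change in each direction among those past the threshold with non-overlapping replicate ranges and a mean of at least 1 CPM in the higher group. It also named up to 4 members per list with the smallest p past the threshold, and the 10 bins of smallest p, at most 1 per gene. Other list members named as not passing, or as further examples, were chosen after their values were seen. For 6 list members the annotation gave no identifier (XIUQIU1 to XIUQIU4, LURE1.7 and LURE1.8), and DD11 was left out because the annotation gives its identifier another name. Lists were tested with camera at the preset correlation of 0.01 and at an estimated correlation, and with fry, in limma 3.58.1.

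The gene test was tested on simulated data with 67 genes changed 1.5-fold, 66 changed 2-fold and 66 changed 4-fold among 19098 tested and recovered 16.4% of 1.5-fold, 57.6% of 2-fold and 98.5% of 4-fold changes, with 12 false calls. The bin test on simulated data with 113975 bins recovered none of the 1.5-fold, 18.8% of the 2-fold and 84.1% of the 4-fold changes of a single bin, with 13 falsely called genes. Changes of 2-fold or less in a bin were therefore mostly out of its reach, and sizes between 2- and 4-fold were not simulated. Alternatives were other scalings, filters and tests (DESeq2 1.42.0, limma-voom), a replicate block, and leaving out each library.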

Results

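The RNA of mature Arabidopsis thaliana ovules was compared between wild type plants and plants carrying insertions in both genes for PRP8, the largest protein of the spliceosome core. The labels write the second genotype as PRP8Aa prp8bb and describe its ovules as a mixture in which PRP8B is disrupted throughout and PRP8A in part. Each group had 3 libraries, numbered 1 to 3, from flowers of stage 13 to 14 on 6-week-old plants. Gene counts per library totalled 8497702, 12436159 and 12460805 in wild type replicates 1, 2 and 3, and 12644525, 11278367 and 11261844 in the corresponding replicates labelled PRP8Aa prp8bb. The first principal component of log counts held 55.1% of the variance and had all 3 wild type libraries on one side and the other group on the opposite side.

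The first comparison asked whether the targeted genes differed between the groups. PRP8A (AT1G80070, TAIR10 chromosome 1, 30117847 to 30127811, plus strand) had 1157 ± 37.7 CPM (SD, n = 3) in wild type and 924.6 ± 47.0 (SD, n = 3) in the other group. Its log2 fold change was -0.32 (SE 0.10, adjusted p = 0.105), which did not pass the threshold of 0.05, although it did with the DESeq2 Wald test (adjusted p = 0.0213). PRP8B (AT4G38780, chromosome 4, 18101296 to 18111082, minus strand) had 36.6 ± 1.76 CPM in wild type and 42.7 ± 1.19 in the other group (SD, n = 3; log2 fold change 0.22, SE 0.10, adjusted p = 0.251). Over their exon bins, the stretches into which annotated exons are divided, the genes were not uniform. A boundary was placed in each gene, after the values had been seen, where the split of the bins into a 5′ and a 3′ part differed most among the 6 libraries. For PRP8A the 3′ part (30124922 to 30127811, 8 of 24 bins) held 29.7 ± 3.04% of the gene's bin counts in wild type and 21.5 ± 1.63% in the other group (SD, n = 3), with no overlap between the groups.

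For PRP8B the 3′ part (18101296 to 18104764, 9 of 25 bins) held 27.8%, 35.7% and 37.8% in wild type replicates 1, 2 and 3. The corresponding values in the libraries labelled PRP8Aa prp8bb were 32.0% (95% Wilson interval 28.9 to 35.2), 6.71% (5.05 to 8.86) and 18.1% (15.6 to 20.9). The first of them lay within the wild type range, so the PRP8B values went against the label of that library, and the third lay between it and the second. For PRP8A that library followed its group (22.6%). Wild type replicate 1 and replicates 2 and 3 of the other group had the lowest PRP8B shares, and also the fewest exon bin counts and the highest mitochondrial shares. An effect of library quality on this share therefore cannot be told apart from a difference of genotype. The group is therefore called the libraries labelled mutant, and every direction given for it includes a library whose PRP8B transcript resembled wild type in this share.

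**Figure D1:**
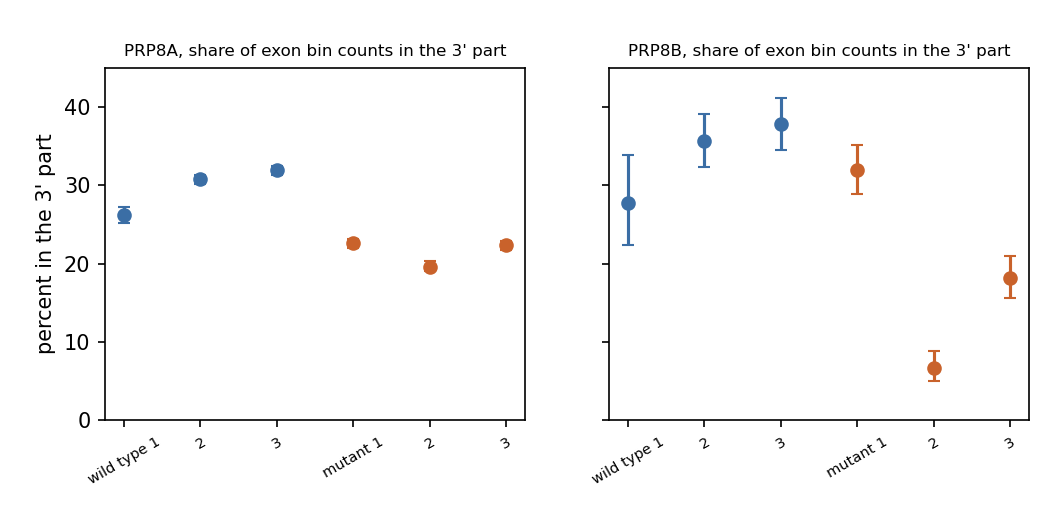
Percent of the exon bin counts of PRP8A and PRP8B that fell in the 3′ part of the gene, 1 point per library. The 95% Wilson intervals take each bin count as independent and are too narrow. The PRP8A values of the libraries labelled mutant lay between 19.6% and 22.6%, below those of all 3 wild type libraries, while for PRP8B the values of that group spread from 6.71% to 32.0%.

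The second comparison asked which genes differed in level between the genotypes. The embryo sac is the female gametophyte that holds the egg cell, the central cell and the synergids. Of 32 measured genes listed for it, 20 fell in the libraries labelled mutant and none rose, and the others did not pass. Among 14 measured genes of the central cell, which gives rise to the endosperm, 10 fell, 4 did not pass and none rose. DD25 fell from 5.10 ± 0.927 to 0.307 ± 0.131 CPM (SD, n = 3; log2 fold change -3.96, SE 0.38, adjusted p = 0.000515). DD36 (log2 fold change -3.53), DD65 (-3.26) and DD41 (-3.24) fell nearly as far, and the Polycomb gene FIS2 fell by 1.71 on the log2 scale. Of 7 measured egg cell genes, 6 fell, among them the aspartic protease gene ECS2 (16.9 ± 1.66 to 5.17 ± 1.47 CPM, SD, n = 3; log2 fold change -1.69) and EC1.4 (-1.92), a member of the family of proteins that the egg cell secretes to activate sperm.

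Of 11 measured genes for synergid function and pollen tube attraction, 4 fell and none rose. LURE1.3 (AT5G43513, chromosome 5, 17477943 to 17478393), a secreted peptide that attracts pollen tubes, fell from 3.68 ± 0.890 to 0.374 ± 0.369 CPM (SD, n = 3; log2 fold change -3.24, SE 0.53, adjusted p = 0.00652), or -4.33 without mutant replicate 3. LURE1.5, in the same cluster (-2.34), DD31 (-2.38) and the annexin gene ANN8 (-1.15) also fell. MYB98, the transcription factor that controls synergid genes, had 2.34, 2.42 and 1.86 CPM in wild type replicates 1, 2 and 3 and 1.59, 0.912 and 0.617 in those labelled mutant and did not pass (log2 fold change -1.05, adjusted p = 0.185). Nor did LURE1.1 (log2 fold change -1.34, adjusted p = 0.0806), NTA (-0.18, adjusted p = 0.842) or the reception kinase gene FER (0.39, adjusted p = 0.0544). FER rose with the DESeq2 Wald test (adjusted p = 0.00910), with no filter on low counts (0.0352), with organelle and rRNA genes left out (0.0470) and without mutant replicate 1 (0.0283), and the authors' deposited table gives it an adjusted p of 0.00844. LURE1.2, LURE1.4 and LRE lay below the count filter. LURE1.2 had 4, 12 and 18 counts in wild type and 2, 0 and 2 in the libraries labelled mutant, LURE1.4 had 14, 9 and 13 against 3, 0 and 3, and LRE had 0, 3 and 2 against 4, 4 and 1. The LURE1 genes are similar tandem copies, so the division of counts among them is uncertain.

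The LURE peptides belong to the defensin-like, cysteine-rich family. Of 45 measured defensin-like genes, 28 fell and 4 rose, with a median log2 fold change of -2.43. LCR19 (log2 fold change -5.38), AT1G77525 (-3.73) and AT2G21465 (-3.52) fell, while LCR17 (3.33) and LCR69 (0.53) rose. The log2 fold change was -6.61 for LCR19 without mutant replicate 3, -4.11 for AT2G21465 without mutant replicate 1 and 3.93 for LCR17 without wild type replicate 1. The list shares 2 genes with the central cell list, DD22 and DD36. Adjusted over the list alone, 12 central cell, 6 egg cell and 6 synergid genes fell and 1 synergid gene rose, and 32 defensin-like genes fell and 4 rose. The camera test against other genes gave adjusted p = 4.26e-13 for the central cell, 1.46e-07 for the egg cell, 0.00864 for the synergid list and 1.62e-21 for the defensin-like list. With an estimated correlation between genes, adjusted p = 0.282 for the egg cell, central cell and defensin-like lists and 0.450 for the synergid list. The rotation test fry gave adjusted p = 0.0122, 0.00750, 0.0254 and 0.00750 for the egg cell, central cell, synergid and defensin-like lists. Without wild type replicate 3 or mutant replicate 3 the fallen egg cell genes numbered 3, without mutant replicate 3 the fallen central cell genes numbered 6, and without either of these libraries 1 defensin-like gene rose.

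**Figure D2:**
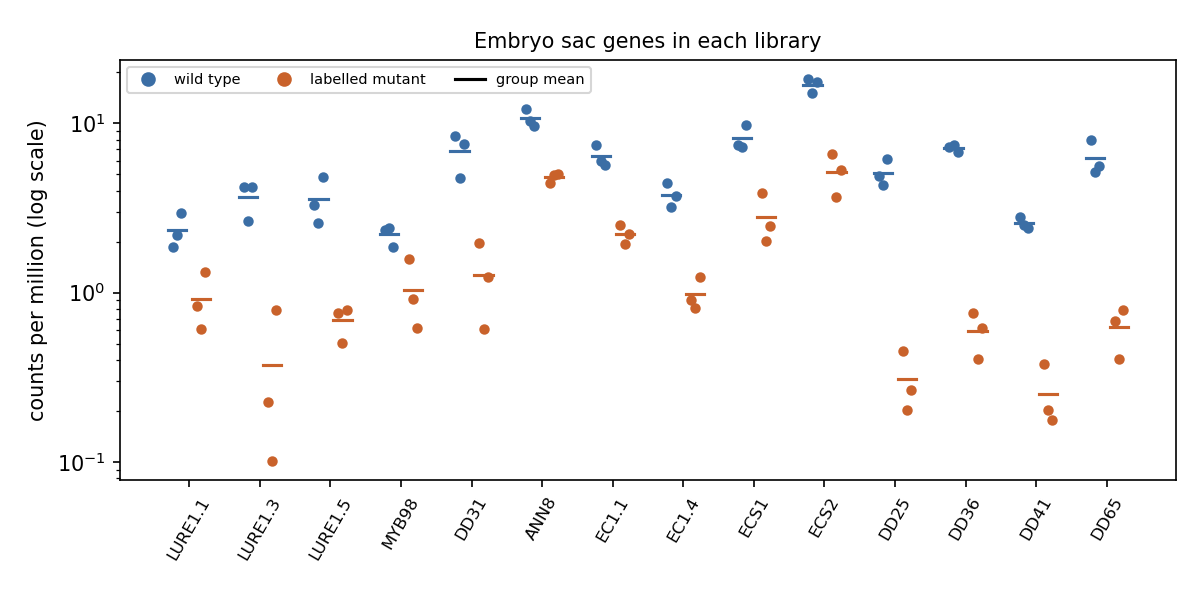
CPM of 14 embryo sac genes on a log axis, 1 point per library, with a line at each group mean. For DD25 the wild type libraries averaged 5.10 and the libraries labelled mutant 0.307, while MYB98 and LURE1.1 did not pass the test.

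Among 14 measured genes of the integuments, the maternal coats of the ovule, and of ovule identity, 5 fell and none rose. BAN, an anthocyanidin reductase gene of the endothelium, fell from 43.8 ± 28.0 to 2.30 ± 1.09 CPM (SD, n = 3; log2 fold change -4.21, SE 0.68, adjusted p = 0.0230). The transcription factor genes TTG2 (-3.14) and TT2 (-2.65), which act in seed coat pigmentation, fell with it, as did the ovule identity genes STK (-0.63) and SHP2 (-0.42). INO (-0.39), ANT (0.32), BEL1 (0.13) and SHP1 (-0.00) did not pass. Of 13 flavonoid pathway genes, 2 fell, namely DFR (-5.19, adjusted p = 0.0497) and LDOX (-4.56, adjusted p = 0.0422), which make the anthocyanidin used by BAN, while CHS (0.16, adjusted p = 0.825) did not pass. Adjusted over the list alone, 10 integument genes fell and 1 rose, and 2 flavonoid genes fell. Camera gave adjusted p = 0.000259 for the integument list (0.496 with an estimated correlation) and 0.0703 for the flavonoid list. The integument list did not pass fry (adjusted p = 0.0798). Wild type replicates 1, 2 and 3 had 15.9, 72.0 and 43.5 CPM of BAN, and the fallen integument genes numbered 8, 3 and 1 without wild type replicate 1, 2 or 3, and 3, 2 and 1 without mutant replicate 1, 2 or 3. With limma-voom BAN (adjusted p = 0.141), TT2 (0.0919), LDOX (0.274), DFR (0.368) and SHP2 lost their calls, and with no filter on low counts BAN (0.0784), LDOX (0.120) and DFR (0.134) did. The DFR call was also lost with upper-quartile factors (adjusted p = 0.0535) and with a filter of 1 CPM in 3 libraries (0.0510). The log2 fold change of TT2 was -3.49 without mutant replicate 1, that of DFR was -4.45 without wild type replicate 2, and that of LDOX was -3.96 without wild type replicate 2 and -5.34 without mutant replicate 1. The flavonoid calls were both lost without wild type replicate 2 or 3 or any library labelled mutant.

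Of 12 measured circadian clock genes, 5 rose and 3 fell. Of the genes with morning expression, CCA1 (-2.31, adjusted p = 0.00591), LHY (-3.53, adjusted p = 0.0164) and RVE8 (-1.97) fell, while PRR9 (-0.51, adjusted p = 0.524), RVE1 (-0.68, adjusted p = 0.416) and PRR7 (0.42, adjusted p = 0.106) did not pass. Of the genes expressed later in the day, ELF3 (0.50, adjusted p = 0.0699) did not pass and the others rose: PRR5 went from 2.86 ± 1.54 to 27.5 ± 2.31 CPM (SD, n = 3; log2 fold change 3.32, SE 0.31, adjusted p = 0.000867), and BOA (2.05), LUX (1.46), GI (1.31) and TOC1 (0.94) rose by less. The clock-regulated RNA-binding protein gene GRP7 rose from 48.1 ± 24.9 to 404.9 ± 130.4 CPM (SD, n = 3; log2 fold change 3.08, adjusted p = 0.0160), and its call was lost without wild type replicate 3, without mutant replicate 2 or 3, or with no filter on low counts (adjusted p = 0.0536). Adjusted over the list alone, 7 clock genes rose and 3 fell. ELF3 passed with the DESeq2 Wald test (adjusted p = 0.0390), with no filter on low counts (0.0300) and without wild type replicate 1 (0.0460). The fallen clock genes numbered 2 without wild type replicate 3, without any single library labelled mutant, or with no filter on low counts. The list, whose members moved both ways, did not pass camera (adjusted p = 0.0703, or 0.525 with an estimated correlation). Fry's test for change in either direction gave adjusted p = 0.000746. That result was not particular to the clock, with 0.000223 for both the touch response and the salicylate list. It was 0.00385 for photosynthesis, 0.0109 for the integument and 0.0158 for the jasmonate list. The spliceosome core (0.0946) and mitotic (0.155) lists did not pass it. Fry values given for other lists elsewhere are those of its test in a single direction.

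**Figure D3:**
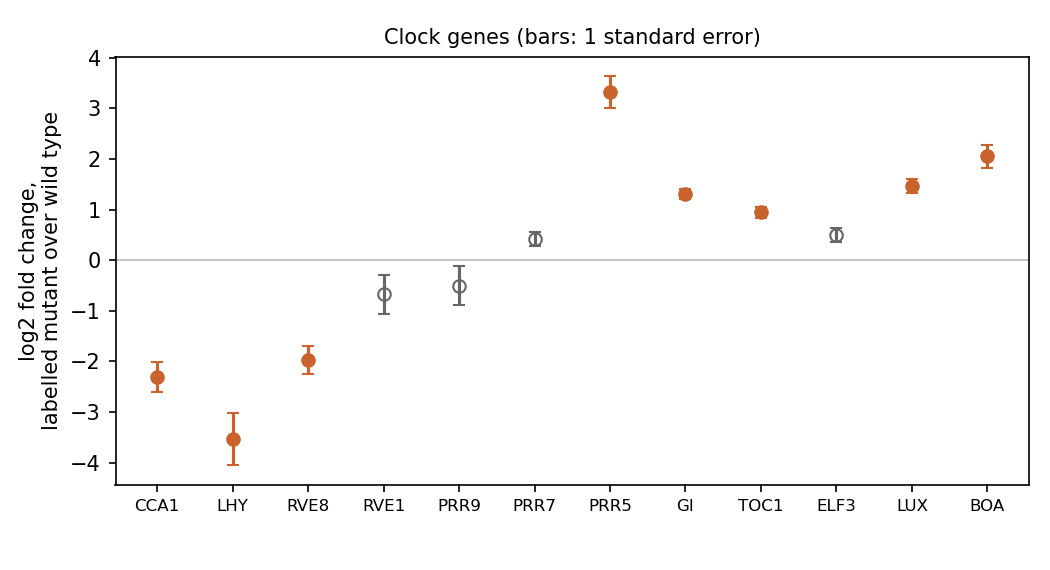
Log2 fold change of 12 clock genes, libraries labelled mutant over wild type, with bars of 1 standard error and filled points for adjusted p under 0.05. LHY lay lowest at -3.53 and PRR5 highest at 3.32.

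Of 17 genes for jasmonate and wounding, 4 rose and none fell: VSP2 from 541.0 ± 62.3 to 1420 ± 278.2 CPM (SD, n = 3; log2 fold change 1.39, SE 0.16, adjusted p = 0.00119), LOX2 (0.95), VSP1 (0.92) and the synthesis gene OPR3 (0.61). Adjusted over the list alone, 9 rose. Camera gave adjusted p = 3.28e-07, with adjusted p = 0.496 with an estimated correlation. The list did not pass fry (adjusted p = 0.0828). The risen genes numbered 2 without wild type replicate 3 or mutant replicate 3, and 9 without mutant replicate 1. They numbered 7 with no filter on low counts, and 6 with the DESeq2 Wald test or with wild type replicate 1 counts halved.

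Genes of other tissues were measured beside these groups. Of 18 pollen genes 2 rose, PPME1 (2.28) and BUPS2 (0.72), of 3 stamen and tapetum genes the petal and stamen identity gene PI rose (1.36), and of 7 carpel genes SPT rose (0.73). Of 17 photosynthesis genes RBCS2B fell (-1.36), and camera placed this list lower (adjusted p = 0.00110, or 0.496 with an estimated correlation). Of 9 heat shock genes HSP17.6A fell (-2.80), and this list also lay lower by camera (adjusted p = 0.0486, 0.0547 with upper-quartile factors and 0.741 with an estimated correlation). Neither list passed fry (adjusted p = 0.0828 for photosynthesis and 0.416 for heat shock). HSP101 had 67.9, 395.0 and 227.4 CPM in wild type replicates 1, 2 and 3 and 66.6, 134.8 and 86.7 in those labelled mutant, and HSP70-4 had 42.3, 382.0 and 208.8 against 46.2, 100.0 and 66.2, so that wild type replicate 1 lay within or below the range of the other group for both. The median log2 fold change of the heat shock list was -1.35, and -0.63 without wild type replicate 2. ERF6 rose (0.92) among 15 touch response genes and PR5 (0.89) among 5 salicylate genes. Adjusted over the list alone, 3 pollen, 2 carpel, 2 touch and 2 salicylate genes rose, 1 stamen gene rose and 1 fell, 2 salicylate genes fell, 3 photosynthesis genes fell and 1 heat shock gene fell. None of 27 other spliceosome core genes and none of 17 mitotic genes passed, over all genes or adjusted over the list alone, and GRP7 was the only one of 21 genes for SR proteins and related regulators that did. BRR2B (0.51) rose with the DESeq2 Wald test (adjusted p = 0.0227), with no filter on low counts (0.0177) and with upper-quartile factors (0.0464). It also rose with organelle and rRNA genes left out (0.0465) and with wild type replicate 1 counts halved (0.0452). RDM16 (0.44) rose with the Wald test (adjusted p = 0.0350), with no filter (0.0300) and with those counts halved (0.0484). GRP8 (1.98) rose with the Wald test (0.0143). AP3 (-0.71), of the stamen and tapetum list, fell with the Wald test (adjusted p = 0.0286) and with no filter (0.0243). It also fell with wild type replicate 1 counts halved (0.0489) and without mutant replicate 1 (0.0410). In the other direction, the pollen gene AGP6 (0.83) rose with the Wald test (0.0111) and the carpel gene NTT (0.63) with no filter (0.0398). Only 1 early seed gene was measured, WOX9 (1.02, adjusted p = 0.0688; adjusted over the list alone, it rose), and it passed with the DESeq2 Wald test (adjusted p = 0.00657) and without mutant replicate 1 (0.00432). Among 172 organelle-encoded genes, ATCG00080 (-0.58) and ATCG00630 (-0.59) fell, and mitochondrial genes took 14.5% of the counts of mutant replicate 2, against 2.43% to 6.53% in the other libraries. Adjusted over the list alone, no organelle-encoded gene passed, and of the pair of PRP8 genes PRP8A fell and PRP8B rose. The PPME1 call was lost with no filter on low counts (adjusted p = 0.0773). The PI call was lost without wild type replicate 2 or 3 or any library labelled mutant, and the pollen calls numbered 0 without wild type replicate 2 or 3 or mutant replicate 3, 1 without mutant replicate 1 and 7 without mutant replicate 2. HSP17.6A lost its call without wild type replicate 2 or 3 or mutant replicate 1 or 3, SPT without wild type replicate 3 and ERF6 without mutant replicate 3. Without wild type replicate 1, 4 heat shock, 4 photosynthesis and 5 organelle-encoded genes fell and 2 spliceosome core genes rose, and without mutant replicate 1, 3 carpel, 3 touch, 3 SR protein list, 4 organelle-encoded and 1 spliceosome core genes rose and 7 organelle-encoded genes fell. Without mutant replicate 2, 3 photosynthesis genes fell. ATCG00080 lost its call when any 1 library was left out and with upper-quartile factors (adjusted p = 0.0543), and ATCG00630 lost its call without wild type replicate 2 or 3 or mutant replicate 3.

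**Figure D4:**
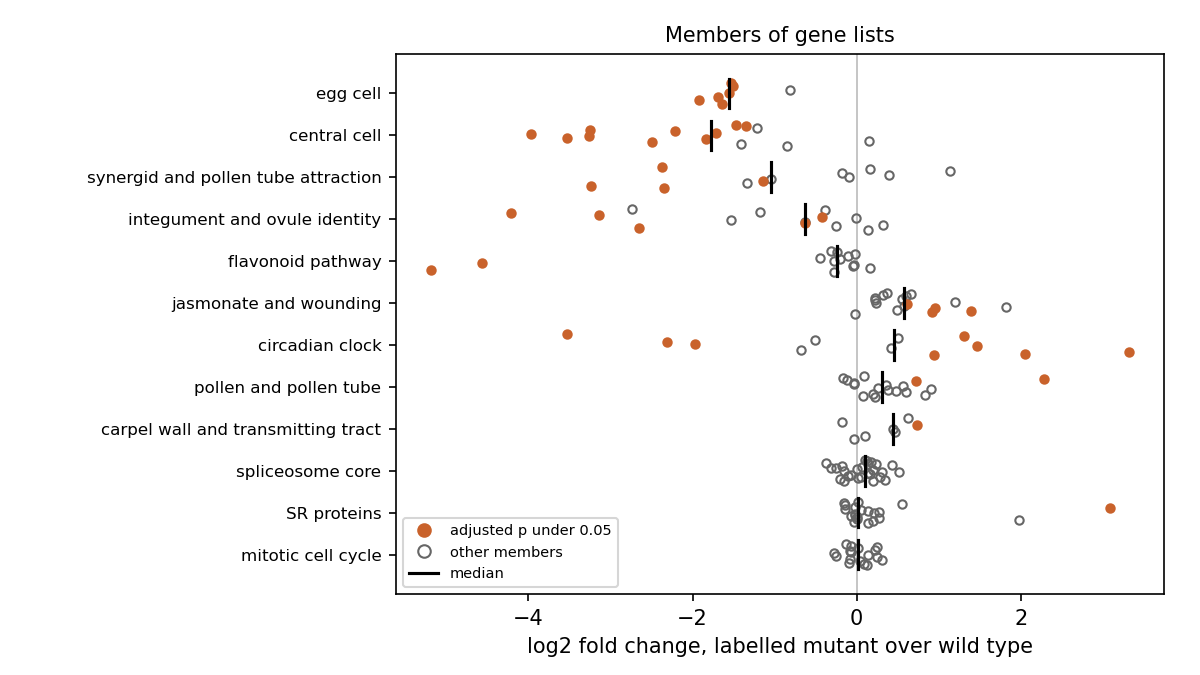
Log2 fold changes of the measured members of 12 gene lists, libraries labelled mutant over wild type, 1 point per gene, filled where adjusted p was under 0.05, with a line at each median. The median was -1.77 for the central cell list and -1.56 for the egg cell list, and 0.10 for the spliceosome core list.

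Over all genes, 589 rose and 539 fell among 19297 tested. Of the genes named for the size of their rise, AT1G21550, an EF-hand calcium-binding protein gene, rose from 0.0776 ± 0.0774 to 7.37 ± 0.856 CPM (SD, n = 3), on a total of 3 counts in wild type (ratio 85.0, 95% counting interval 28.8 to 415.0). The cytochrome P450 gene CYP705A2 (ratio 89.7, interval 16 to 3581), the VQ motif gene AT1G35830 (81.7, interval 14.3 to 3266), AT3G50120 (49.8, interval 8.54 to 2007), the cuticle regulator SHN1 (40.9, interval 6.93 to 1653) and AT4G35720 (32.6, interval 10.8 to 160.6) also had at most 3 counts in wild type. Without wild type replicate 3 no wild type counts were left for CYP705A2, AT1G35830 and AT3G50120, which were then at least 18.6-, 17- and 10.4-fold higher (floor of 3 counts over the group), and without wild type replicate 2 the same held for SHN1 and AT4G35720, at least 8.53- and 20.4-fold higher. Without wild type replicate 2 the ratios of the first 3 were 56.2, 51.2 and 31.2, and without wild type replicate 3 those of SHN1, AT4G35720 and AT1G21550 were 25.5, 20.3 and 159.0, each inside its interval. AT3G12000, a relative of S-locus genes, rose from 8.14 ± 6.97 to 286.0 ± 23.9 CPM and the E6-like gene AT2G33850 from 10.4 ± 8.97 to 284.0 ± 43.5 CPM (SD, n = 3). AT4G13266 rose from 0.258 ± 0.272 to 16.2 ± 4.17 CPM (log2 fold change 5.90) and the malate transporter family gene AT4G00910 from 0.545 ± 0.743 to 13.2 ± 4.28 CPM (4.83; SD, n = 3). Single wild type libraries moved the size of these 4 changes. Without replicate 1 the log2 fold change of AT4G00910 was 6.69, that of AT3G12000 went from 5.20 to 5.95 and that of AT2G33850 from 4.82 to 5.60, while that of AT4G13266 was 5.26 without replicate 2 and 7.27 without replicate 3.

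The 10 genes named for the size of their fall had no counts in any library labelled mutant, so their change is a bound against a floor of 3 counts over the group. The laccase-related gene sks8 was at least 85.3-fold lower, the subtilase gene AT5G58840 at least 44.2-fold, the expansin gene EXPA25 at least 39.5-fold, RR22 at least 34.8-fold, AT4G33840 at least 31.1-fold, the cysteine-rich protein gene AT3G04545 at least 26.8-fold, the carboxypeptidase-like gene scpl21 at least 24.4-fold, the peroxidase gene PRX52 at least 24.1-fold, AT1G64107 at least 19.4-fold and the defensin-like gene AT1G63522 at least 17-fold. Without wild type replicate 2 the bound was 17.1-fold for AT4G33840 and 57.2-fold for sks8. Without mutant replicate 1, where 3 counts are a larger share of the counts left in the group, the 10 bounds ran from 10.7-fold for AT1G63522 to 52.5-fold for sks8, and that of AT4G33840 was 19.2-fold. Calls were those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05. Without wild type replicate 3 the count of genes that passed fell from 1128 to 455, and without mutant replicate 3 to 431, and 22 and 21 of the 60 named genes past the threshold lost their call, sks8, EXPA25, AT4G33840, AT3G12000 and AT2G33850 among them in both cases. With no filter on low counts sks8 and AT2G33850 also lost their calls, and with upper-quartile factors sks8 did (adjusted p = 0.0519). The authors' deposited table lists 1543 genes, 779 with a positive and 764 with a negative log2 fold change, of which 1114 passed here with the same sign, and it gives PRP8A an adjusted p of 0.0192 at a log2 fold change of -0.32.

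The third comparison asked whether exons were used differently, as a change in splicing would show. Of 116071 exon bins tested in 14868 gene groups, 2 passed, both lower in the libraries labelled mutant and both in the merged group of the neighbouring genes PHS2, an alpha-glucan phosphorylase, and PHT4;3, a phosphate transporter. The first bin lay on chromosome 3 at 17307416 to 17307595 (minus strand) with a usage log2 fold change of -1.01 (adjusted p = 0.00173), and the second at 17308627 to 17308990 with -0.87 (adjusted p = 0.0329). The first had 19, 76 and 70 counts in wild type replicates 1, 2 and 3 and 70, 34 and 39 in those labelled mutant, before any scaling for the lower depth of wild type replicate 1. Mutant replicate 1, with 22353729 bin counts in total, thus held as many as wild type replicate 3, with 22552397. In the second bin these libraries had 72 and 77 counts. These are raw counts, not usage within the group. In such a merged group, a change in the level of 1 gene also changes the share of its bins. PRP8A (24 bins) and the group holding PRP8B (25 bins) had no bin past the threshold, and none of the 27 spliceosome core, 21 SR protein or 12 clock genes tested passed per gene.

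Bins were tested with edgeR's diffSpliceDGE, and 1844 bins were under an unadjusted p of 0.05. Without mutant replicate 1, 47 bins passed, without wild type replicate 1 12 passed, and without mutant replicate 2 5 passed. Without wild type replicate 2 or 3 or mutant replicate 3 none did. Leaving out mutant replicate 1 keeps mutant replicates 2 and 3, which with wild type replicate 1 had the highest mitochondrial shares. A split of those libraries against the rest gave 62 bins, so the 47 bins cannot be assigned to the genotype. No gene outside a merged group passed the bin test, so its overlap with the 729 genes that changed in level, among 14177 genes in both tests, was 0 and could not be tested in substance (Fisher's exact test, two-sided, p = 1). The retention ratios of the intron table were not compared between the genotypes, because that table names no sample. The share of exon bin counts in annotated retained introns is given under the other observations.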

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

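The retention ratios of the intron table, which no comparison used, held a signal outside the main measurement. Of 55285 introns without a warning and with a total depth of at least 10, 4642 (8.40%) had a retention ratio of at least 0.1, and the median ratio was 0.0161. The table names no sample and there is no control beside it, so these values belong to no genotype. With 3 libraries per group, no search for outlying libraries within a group was made.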

How the results depend on the processing

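The halved counts, the limit to groups of 1 gene, list counts, bounds and ratios without single libraries and the overlap under other fits were chosen after the data were examined. The 1128 genes that passed became 676 with an absolute log2 fold change of at least 1, by construction, and 431 to 1399 with 1 library left out. Under the other scalings, filters, tests and halved counts they numbered 1047 to 1531, with 50.3% to 53.6% of them higher in the libraries labelled mutant. The 2 bins became 5 with limma-voom diffSplice, 0 in gene groups of 1 gene only, where the merged group is absent, and 0 to 47 with 1 library left out. The 8 lists past camera's threshold became 0 with an estimated correlation. Replicate numbers did not pair the libraries: same-numbered libraries had correlations of deviations of -0.05, -0.05 and 0.10, and not every library correlated best with its own number. With a replicate block 886 genes, 1 bin and 10 lists passed, and 9 named calls were lost. No named call reversed. The cause of the other changes was not tested. The planned tests of intron retention and their alternatives were not run, because the table names no sample. At these depths the bin test recovered 18.8% of simulated 2-fold changes. The effect of depth itself on the number of bins was not tested.

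The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 1128 genes and no other gave any (1 of 10 as large). Every other split mixes the genotypes, so their difference adds to the spread within its groups, and the lack of calls there decides nothing. The real split gave 2 bins, and 2 of 10 splits gave as many. The highest other, 62 bins, set wild type replicate 1 and mutant replicates 2 and 3 against the rest, which points to a structure of the samples. These libraries had the fewest bin counts, the highest mitochondrial shares (6.53%, 14.5% and 4.88%, against 2.43% to 2.98%) and the lowest plastid shares (8.91%, 6.48% and 8.83%, against 10.7% to 11.6%). It gave 8 lists, and 3 of 10 splits gave as many, the highest other 10.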

Other observations

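The tests of the clock outputs, the exon bins of clock genes and the genes matched on length were set before their results were seen; the tests of embryo sac loss, dilution, early seed genes and carpel tissue were chosen afterwards. The share of annotated retained introns was compared between the groups. In 5140 genes with a bin that coincides with an intron of the intron table, such bins held 3.64 ± 0.0966% of the gene's bin counts in wild type and 3.54 ± 0.0624% in the libraries labelled mutant (SD, n = 3), a difference of -0.101 percentage points (exact permutation test, two-sided, p = 0.3, smallest possible 0.1). Of 2324 such bins with enough counts, 1070 had a higher and 1254 a lower share. Of 17 measured output genes of the clock, listed beforehand, 6 passed and 11 did not. Of the morning genes, COL2 (-2.41), COL1 (-1.59), LNK2 (-1.19) and RVE4 (-0.59) fell, and of the evening genes, FKF1 (3.01) and PRR3 (2.25) rose. The morning genes CAT2 (-0.02), LNK1 (-0.34), CDF1 (-0.32), RVE7 (-0.14), RVE6 (-0.17), SIG5 (-0.56) and PIF4 (0.60) and the evening genes CAT3 (0.97), COR27 (1.83), WNK1 (0.04) and CKB4 (-0.20) did not pass, PIF4 and CKB4 with the opposite sign to the genes that did. CAT3 (adjusted p = 0.000431) and COR27 (0.0183) passed with the DESeq2 Wald test, COR27 with no filter on low counts (0.0231), CAT3 without wild type replicate 1 (0.00748) or 2 (0.0261), COR27 without mutant replicate 2 (0.00820), and SIG5 without wild type replicate 1 (0.0201) and with that library's counts halved (0.0456).

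The clock genes that changed were lower for the morning and higher for the evening in the libraries labelled mutant. Changed exon usage of these genes was not detected, with 0 of the 8 past the bin test per gene, but that test found 18.8% of simulated 2-fold changes and decides nothing. Over 6 evening and 11 morning output genes listed beforehand, the median log2 fold change differed by 1.74 (exact permutation test over genes, two-sided, p = 0.0017, genes not being independent replicates). This is consistent with a different clock phase in the whole tissue. No label gives the hour of harvest and no series of hours was sampled. A shift of phase therefore cannot be told apart from a change in the level of the clock genes alone. Whether the harvest or the genotype set the difference stays open.

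The fall of embryo sac genes may have several sources. A loss of short transcripts is argued against by 517 genes matched on length and expression, whose median log2 fold change was -0.055 (quartiles -0.37 and 0.22), against -1.52 for the members of the egg cell, central cell and synergid lists. The matched genes follow the lengths of all members (median 844 bases), long ones included. A loss confined to the shortest transcripts could therefore be missed. Equal loss of embryo sacs was compatible with the egg cell list, where the 7 log2 fold changes scattered no more than their errors around -1.58 (Q over its degrees of freedom 0.822). The central cell list scattered more (29.3, or 8.11 without the broadly expressed DME). Equal loss gives equal changes only in genes expressed in the embryo sac alone. Expression elsewhere was not tested, so the wider scatter does not decide against equal loss. This test looked only at the scatter of the changes, not at their size. The labels give PRP8A as disrupted in part of the mixture. If PRP8Aa puts the disruption in 1 of 2 embryo sacs, their loss alone lowers a gene by at most 1 in log2. The weighted mean was -1.58 (SE 0.11, members from -1.92 to -0.82) for the egg cell list. It was -2.21 (SE 0.10, members from -3.96 to -0.85) for the central cell list without DME. For these genes as sets, the values argue against that loss as the whole source, with genes not being independent. The share of embryo sacs with the disruption was not tested. Dilution by other floral tissue was examined with the 14 integument and ovule identity genes. Of these, 8, among them INO (-0.39) and STK (-0.63), lay over 2 standard errors above the upper bootstrap bound of the embryo sac median (-1.24). The list medians differed by 0.894, with a bootstrap interval from -0.83 to 1.36. Whether those 8 genes are also expressed in such tissue, where dilution would not lower them, was not tested. The count of 8 therefore does not decide against dilution as the whole source. Some genes of other floral tissue rose: 2 of 18 pollen genes, 1 of 3 stamen and tapetum genes and 1 of 7 carpel genes. The others did not pass. Of the 3 stamen and tapetum genes, 2 had a positive log2 fold change and AP3 a negative value (-0.71). The tissue of AT3G12000 and AT2G33850, which rose to 286.0 and 284.0 CPM, was not examined. Dilution stays open, and a direct effect of the genotype on the embryo sac genes was not tested and stays open too.

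BAN, TTG2, TT2, DFR and LDOX were lower in the libraries labelled mutant and spread widely among the wild type libraries. More carpel wall tissue in wild type is argued against by the carpel list, whose median log2 fold change was 0.447. A candidate explanation is that the wild type libraries held some fertilised ovules. Of 40 counts of 7 early seed genes below the filter, 95% lay in wild type (exact interval 83.1 to 99.4), against 48.7% of all counts: PHE1 had 2, 8 and 1 counts in wild type replicates 1, 2 and 3 and none in the other group, and MINI3 had 0, 5 and 6 and none. The share of all counts is that of an unchanged gene. A gene that fell as far as the embryo sac gene DD25 (log2 fold change -3.96) would also hold most of its counts in wild type. The test therefore cannot tell fertilised ovules from such a fall. The counts are few and were seen before the test was chosen, and WOX9 of the same list went the other way (log2 fold change 1.02). An effect of the genotype on the ovule coat stays open.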
